A study of Mus musculus with 9 samples.

How the data were processed

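Livers of 4 miR-122 knockout and 5 floxed littermate mice, all 6 weeks old, were sequenced after polyA selection. The RNA came from the part of each pulverised liver that was not crosslinked, per the labels' protocols. Samples were grouped by the genotype in their labels, and sex was taken from the same labels. Per the submitters' processing notes, kallisto and sleuth were used with mm10; their versions, the transcript set, the bootstraps and any filter are not given in the sources used here.

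The analysis used 1 table of 30519 transcripts, 1 per gene, of which 98.5% of gene identifiers matched a symbol in GENCODE M21. Its per-library columns are treated as a normalised signal: the deposited values sum, in units of M (mega), to 0.765 ± 0.073 in KO and 1.011 ± 0.115 in WT libraries, so they are not TPM, and they behave as abundances divided by a size factor per library. The design fixed before the data were examined had foreseen TPM or sleuth columns, so the test it named for TPM was applied to these values. The p-value and q-value columns were deposited by the authors for 13540 transcripts, and the p equals a normal p of the coefficient over its standard error to within 0.48%. The coefficient, its standard error and the mean observation are on a natural log scale, per the file headers and the values: the deposited coefficient equals WT minus KO in natural log units and was multiplied by -1 and converted to log2 here. From p and q, the submitters' adjustment ran over 28515 transcripts (58.8% of ranks came out whole within 0.01, next best 2.5%). How the single transcript of each gene was chosen is not given in the sources used here, so a change of a gene can be a change of 1 isoform. The table holds 93.0% of the 100 transcripts with the smallest p and 32.2% of the last part of the ranking.

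Depth was read from the smallest step between low values together with the mean observation. This gave 15.4 to 22.0 M reads in KO and 12.2 to 19.7 M reads in WT libraries on the listed transcripts. Between 55.3% and 65.2% of low values (up to 10 reads) were whole within 0.1 read. The rule for choosing among ambiguous steps was set after they were seen. No count test was the main test, since kallisto's estimates are not whole reads. No library pair had identical values, and the highest Pearson r of log2 values between libraries was 0.986.

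Transcripts with a mean of at least 1 over the 9 libraries were tested on log2(value + 1) with limma 3.58.1 (R 4.3.3), with genotype as the only term, a trend in the prior variance and Benjamini-Hochberg adjustment at 0.05 over 10950 transcripts. A log2 fold change on this scale understates the change of low transcripts, and folds in the text are ratios of means. Each animal is 1 replicate, and the labels do not say which animals share a litter. Gene lists (35 fixed before the data were examined, 34 with at least 3 tested members) were tested with camera at a correlation of 0.01, two-sided, and again with an estimated correlation, beside cameraPR, fry and Fisher's exact test. The X inactivation list, whose 1 member is Xist, was not analysed here, nor were miR-122, its host and H19.

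Genes were named by a rule fixed before the data were examined. It takes the 12 largest increases and the 12 largest decreases among called transcripts above the median abundance, up to 4 members with the smallest adjusted p on each side of a list, and Aldoa, Slc7a1, Ccng1, Afp, Igf2, H19, Mttp, Cidec and Ago2. Some genes that the rule or the plots would include are not reported here. Numbered predicted genes, clones and pseudogenes were left out. Rps12l1 was left out as a processed pseudogene by its annotated type, a reading of the rule decided after its value was seen.

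Seed sites of miR-122-5p were searched in the annotated 3' UTR of each transcript (GENCODE M21, GRCm38, the assembly that mm10 names) of at least 50 bases. This left 12129 genes, 89.6% of those with a coefficient. Differences of medians were tested with 10000 permutations within 10 bins of UTR length, and all possible words of 7 bases were ranked in a linear model with log UTR length and GC content. Coordinates are 1-based.

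The limma step was tested on simulated data with the group sizes of this comparison (10950 genes, 200 changed): 83% of log2 changes of 1 and 94% of changes of 2 were recovered, and 12 of 189 calls (6.3%) were false. The simulated genes were drawn independently, with no sex effect and few changes, so these rates need not hold for the real libraries. The seed step was tested on shuffled coefficients of 12129 genes. A planted shift of 0.5 gave a difference of 0.471 and rank 1, and with none planted the p was 0.447 and the rank 6759.

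Alternatives fixed before the data were examined were other thresholds, filters, pseudocounts, a minimum size, Bonferroni adjustment, leaving out each library, a replicate block, sex as a covariate, males alone, other inter-gene correlations, other list statistics, and other site types, regions and length bins. For the lists, of these only the correlations, the statistics and the abundance filter were fixed, and for the sex-biased lists only the correlations. Their other settings, males alone with an estimated correlation, equal library totals, voom on recovered reads, adjustment over the submitters' number of tests, the submitters' own q, genes with 1 annotated transcript, the column's sex for WT replicate 3, limma fold changes for the seed tests, the seed shift without the published targets and the genotype by sex term were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the other steps.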

Results

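Liver RNA of 9 mice aged 6 weeks was measured by polyA RNA-seq: 4 miR-122 knockout (KO) animals and 5 floxed littermates, which served as controls (WT). miR-122 is the most abundant microRNA of hepatocytes, and the series paired this RNA-seq with Argonaute CLIP, which maps where Argonaute proteins and their microRNAs sit on transcripts. The comparison asked which transcripts differ in abundance when the microRNA is gone. The KO group held 1 female and 3 males, and the WT group held 3 females and 2 males. Reads recovered from the values on the listed transcripts, in units of M (mega) reads, came to 15.4 to 22.0 in KO and 12.2 to 19.7 in WT libraries, with both WT males lowest at 12.7 and 12.2. WT replicate 3 is labelled female, although its column in the table is named male. The Y-linked genes Ddx3y, Uty and Eif2s3y lay at 0.042, 0 and 0.114 in that library and at 2.36 or above in every male library, so the label female was kept. miR-122 itself and its host transcript were not analysed here, so the genotype rests on the labels. Each gene was represented by 1 transcript. All values are normalised abundances given as mean ± SD over the 4 KO and 5 WT livers.

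The first principal component held 46.7% of the variance and separated every KO from every WT library. The second held 21.3% and placed the 3 WT females (13.87 to 26.40) apart from the 2 WT males (-20.14 and -43.14), while the KO libraries lay between -9.76 and 14.23.

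**Figure D1:**
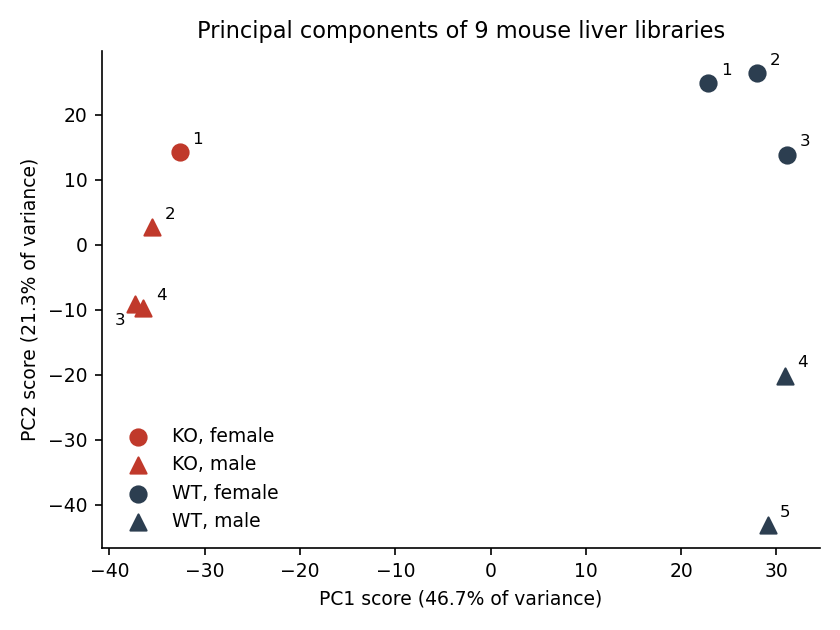
Scores of the 9 libraries on the first principal component (x axis, 46.7% of variance) and the second (y axis, 21.3% of variance) of log2 abundances; each point is 1 library, numbered by replicate, coloured by genotype and shaped by sex. KO libraries lie at -32.62 or below on the first component and WT libraries at 22.86 or above.

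Loss of miR-122 went with a broad change of the liver transcriptome. Of 10950 transcripts tested, 3934 (35.9%) differed between the genotypes at an adjusted p of 0.05 (limma, Benjamini-Hochberg), 2345 higher and 1589 lower in KO. Among these, 570 were at least 2-fold higher and 158 at least 2-fold lower. The lowest value of 1 genotype lay above the highest of the other for 3402 transcripts (31.1%), against 1.59% by chance. Per the authors' deposited table, the submitters' own test called 3413 of 13540 transcripts, 1842 higher and 1571 lower in KO, and the 2988 called by both tests all had the same direction. The balance of higher and lower calls depended on abundance and scaling. Among transcripts above the median abundance 1196 were higher and 1355 lower. With every library scaled to equal totals, an alternative chosen after the data were seen, 4926 transcripts were higher and only 298 lower. The median of all log2 fold changes moved from 0.03 to 0.36. Of the 3934 calls, 2642 were called on both scales, all in the same direction, and 1292 were lost. The fold change of 354 of the 3934 changed sign, none with a call in the new direction. Directions below are on the deposited scale, and a list whose median changes sign on the other scale is named as such.

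Among the 12 largest increases, Igf2, the fetal growth factor (ENSMUST00000000033, chromosome 7, 142650766 to 142666816, minus strand, GRCm38), stood at 961 ± 480.0 in KO against 1.78 ± 0.459 in WT, a 539-fold difference of means (limma adjusted p = 1.22e-07). Meg3, a maternally expressed imprinted RNA, stood at 100.4 ± 30.8 against 0.910 ± 0.323. Lcn2, a siderophore-binding protein, reached 579 ± 127 against 27.2 ± 22.3, and Spp1 (osteopontin) reached 709.5 ± 188.5 against 40.6 ± 10.4. The tetraspanin Cd63 was 10.4-fold higher (88.8 ± 5.33 against 8.52 ± 2.06), and the protease inhibitor Slpi stood at 37.8 ± 6.19 against 0.566 ± 0.622. The other genes among the 12 with the largest increases were Cib3, Ly6d, Plet1, Gipc2, Mfge8 and Afp, each at least 15.2-fold higher by its means.

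**Figure D2:**
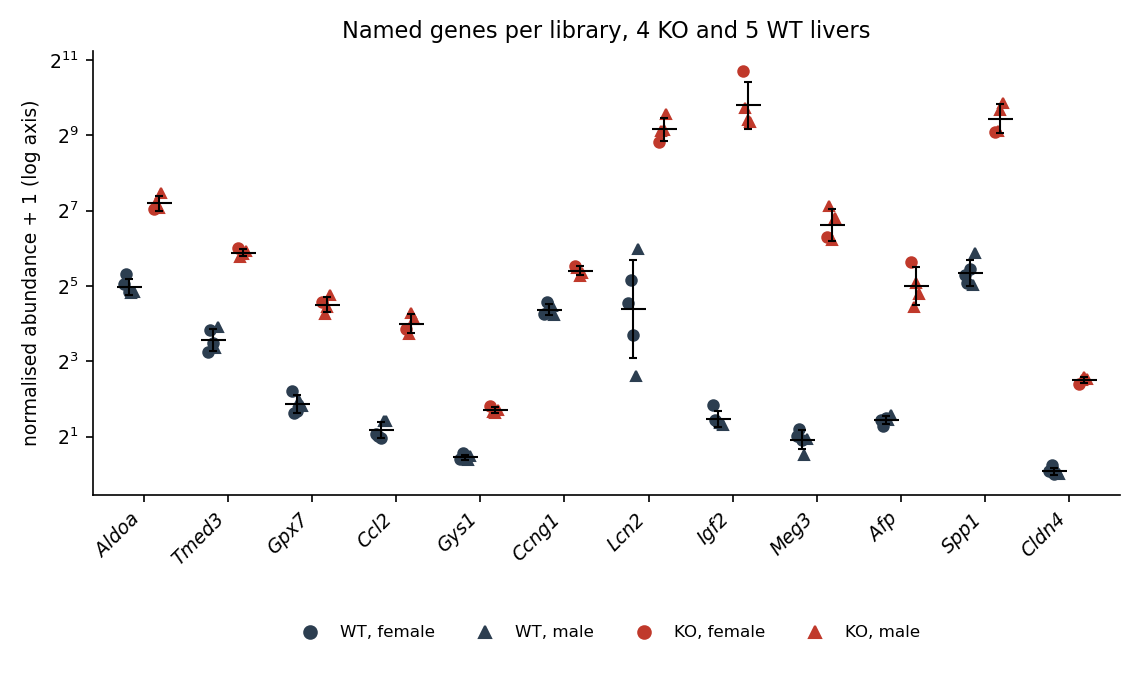
Normalised abundance plus 1 on a log axis (y) of 12 named genes (x) in each library; circles are females, triangles males, and black bars give the mean ± SD of log2 values over 5 WT or 4 KO livers. For each of these genes the lowest KO value lies above the highest WT value, as for Aldoa (130.9 in KO, 38.9 in WT).

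Among the 12 largest decreases were 4 Cyp2c and 2 Mup genes, members of multigene families whose reads can be shared between near-identical copies, so the values of single members are uncertain. Cyp2c40 and Cyp2c67, members of a cytochrome P450 family, stood at 56.2 ± 67.8 against 675.5 ± 324 and at 30.3 ± 3.59 against 298.5 ± 116. Cyp2c40 stood at 157 in the KO female, at 13.6 to 31.3 in KO males and at 279 to 581 in WT males. Cyp2c69 stood at 211 in the KO female, 5.73 to 12.6 in KO males, 75.1 to 191.7 in WT males and at least 456.7 in WT females. The means of these 2 genes therefore mix sex with genotype. Sult2a8, a hepatic sulfotransferase, was 5.86-fold lower (103 ± 26.3 against 601 ± 69.3), Kyat3 was 4.97-fold lower, and Slc3a1, a subunit of an amino acid transporter, was 6.04-fold lower. Ces3b, Cyp2c38 and Wfdc21 were 9.90-fold, 36.3-fold and 4.16-fold lower. Eif4ebp3 lost its call among males alone (limma adjusted p = 0.067). The calls of 3 further genes rest on few libraries. Mup19, a major urinary protein, lay at 24.6 in KO replicate 3 and at or below 0.0335 in the other KO livers, with 6440 in WT replicate 5, and voom on recovered reads, chosen after the data were seen, did not call it (adjusted p = 0.328). Mup18 (limma adjusted p = 0.0311) was not called without KO replicate 1, 2 or 4 or WT replicate 2, 3, 4 or 5 (0.0531 to 0.0818). Cyp2c69 was not called without KO replicate 3 (0.0518).

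Published targets of miR-122 rose together. Of 32 targets tested, 27 were higher in KO and none was lower, adjusted over all genes and adjusted over the list alone (camera adjusted p = 4.16e-12; 0.00229 with an estimated correlation). Aldoa, the glycolytic enzyme often used as a readout of miR-122, stood at 146 ± 20.5 against 30.6 ± 5.11, 4.79-fold higher. The chemokine Ccl2 (15.2 ± 2.86 against 1.29 ± 0.351), the peroxidase Gpx7 (21.9 ± 3.26 against 2.66 ± 0.641) and the cargo receptor Tmed3 (58.1 ± 4.11 against a WT range of 8.56 to 13.9) were 11.8-fold, 8.23-fold and 5.28-fold higher. Ccng1, a cyclin-like protein, was 2.10-fold higher (41.5 ± 3.57 against 19.8 ± 2.06, limma adjusted p = 4.26e-05). Slc7a1 lay below the filter on low values, at 0.7495 ± 0.121 against 0.198 ± 0.0517, and carried a q of 3.09e-05 in the authors' deposited table. The 5 targets without a call were Foxj3, Xpo6, Cux1, Gtf2b and Entpd4, named after their values were seen.

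Transcripts with sites for the seed of the microRNA lay higher in KO than those without. The mature strand is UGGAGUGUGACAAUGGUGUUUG, and transcripts were grouped by the best match of their 3' UTR to bases 2 to 8, from the 8mer ACACTCCA down to the 6mer CACTCC. Among 12129 genes, the median log2 fold change computed from the coefficients of the authors' deposited table was 0.40 higher for 348 genes with an 8mer than for 8872 genes without a site. The difference was 0.29 for 656 genes with a 7mer-m8, 0.23 for 727 with a 7mer-A1 and 0.10 for 1526 with a 6mer. Each had a two-sided permutation p of 0.0001 within 10 bins of UTR length, the smallest that 10000 draws can give, and genes are not independent replicates. Of 247 genes with an 8mer that entered the limma test, 111 (44.9%) were higher and 14 lower in KO, against 1407 (19.2%) higher and 1209 lower of 7340 genes with no site (Fisher's exact test of higher calls, p = 1.81e-19). Among all possible words of 7 bases, ACACTCC and CACTCCA ranked 1 and 2 for higher abundance in KO after adjustment for UTR length and GC content (t of 9.89 and 8.16). UTRs with an 8mer were longer (median 2555 bases) than those with none (median 726 bases). Sites in the coding sequence also went with a higher median, by 0.185 (3808 genes with and 8667 without). For any site in the 3' UTR the difference was 0.193. The mean difference over the permutations was 0.032 for the coding sequence and -0.016 for the 3' UTR. Genes with sites in both regions were not set apart, so these values do not separate the regions.

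Of 34 published targets with an annotated 3' UTR, 27 held at least 1 site and 8 held an 8mer. The Aldoa site lies at 126795383 to 126795390 on the minus strand of chromosome 7 (GRCm38), 29 bases into a 3' UTR of 185 bases, in the context GCTGCTCCATCAACACTCCAGGCCCCTG. The Ccng1 site lies at 40749051 to 40749058 on the minus strand of chromosome 11, in a 3' UTR of 2316 bases (AGGCTTGATAAAACACTCCAGACATTTT). The glycogen synthase gene Gys1 (2.25 ± 0.195 against 0.367 ± 0.0682) holds an 8mer at 45455511 to 45455518 on the plus strand of chromosome 7 (CCTCTGTTTCAGACACTCCAGCCCTTGA). Slc7a1 holds 2 such sites on the minus strand of chromosome 5, at 148332102 to 148332109 and at 148328374 to 148328381. Ccl2 has no site in its annotated 3' UTR of 275 bases, and the best match in that of Gpx7 is a 6mer.

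**Figure D3:**
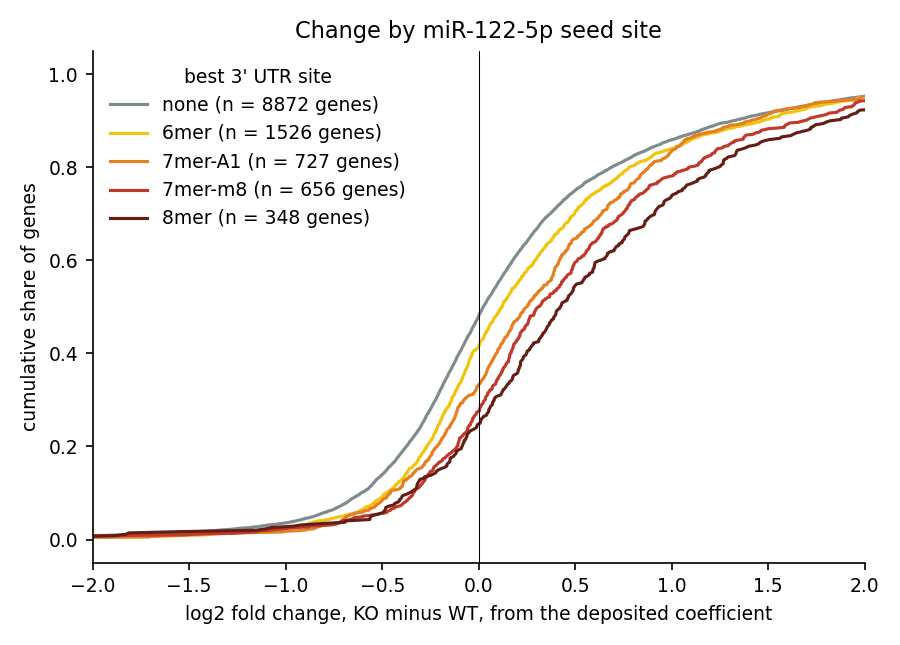
Cumulative share of genes (y axis) by log2 fold change, KO minus WT, from the deposited coefficient (x axis, shown from -2 to 2), for genes grouped by the best miR-122-5p seed match in the 3' UTR. The curve of the 348 genes with an 8mer lies farthest right, with a median of 0.43, and that of the 8872 genes without a site has a median of 0.02.

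With the published targets included, 34 gene lists fixed before the data were examined were compared with all other tested genes. Camera was used with a preset correlation of 0.01 between genes. 10 lists were called higher and 7 lower in KO. With a correlation estimated from the 9 libraries, 2 calls held, those of the targets and of the cholangiocyte and progenitor markers. Counts of members are adjusted over all genes, and the count adjusted over the list alone was the same where none is given. They cover only members that passed the filter on the mean of all 9 libraries. A member near 0 in WT passes only if it is high in KO, which favours increases in lists of low transcripts. Of the listed members, 6 of 20 lymphocyte, 9 of 14 cholangiocyte, 4 of 12 neutrophil and 24 of 31 matrix genes were tested. Camera pointed against the mean or the median of 5 lists that were not called: triglyceride and lipid droplet, glycolysis, acute phase, xenobiotic and microRNA pathway genes.

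Genes of cholesterol and fatty acid synthesis fell. In the cholesterol list 14 of 25 members were lower and none higher (17 lower adjusted over the list alone; camera adjusted p = 2.07e-06, adjusted p = 0.336 with an estimated correlation). The sterol oxidase gene Msmo1 stood at 43.9 ± 6.77 against 127 ± 21.4 and Hsd17b7 at 12.6 ± 2.40 against 24.3 ± 2.49. In the fatty acid synthesis list 10 of 13 members were lower and none higher (10 lower and 1 higher adjusted over the list alone; camera adjusted p = 9.98e-05, adjusted p = 0.24 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, was 4.50-fold lower (159 ± 45.3 against 714 ± 242), Acly was 2.58-fold lower and Elovl6 was 1.96-fold lower. With equal totals 4 cholesterol genes and 7 fatty acid synthesis genes were called lower, and 1 of the latter list was called higher.

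Lists of lipid storage and lipoproteins moved both ways and were not called. Of 20 triglyceride and lipid droplet genes 2 were higher and 1 lower (camera adjusted p = 0.72), with the acyltransferase Agpat1, itself a published target, at 7.31 ± 2.86 against 0.451 ± 0.863 and the monoglyceride lipase Mgll at 23.9 ± 6.84 against 44.9 ± 11.1, a call lost among males alone (limma adjusted p = 0.164) and with equal totals (0.159). Cidec, a lipid droplet protein, stood at 1.99 ± 0.882 against 1.40 ± 1.00 (limma adjusted p = 0.369). Of 20 lipoprotein genes 4 were higher and 6 lower (camera adjusted p = 0.488). Mttp, which loads lipid onto apolipoprotein B, was 1.58-fold lower (71.0 ± 7.05 against 112 ± 14.6, limma adjusted p = 0.00217), a call lost among males alone (0.0801) and with equal totals (0.257). Lcat, which esterifies cholesterol on lipoproteins, was 2.07-fold lower, whereas Apoa4 and the lipoprotein lipase gene Lpl were 1.84-fold and 2.24-fold higher, the latter not called among males alone (0.0673). The medians of both lists change sign with equal totals, to 0.31 and 0.30.

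The lists of bile acid, fatty acid oxidation, amino acid and hepatocyte identity genes were called lower with the preset correlation but not with an estimated one. Each had under 50% of its members called lower, and the medians of the first and the last change sign with equal totals. At set correlations of 0.05 and 0.1 the first 2 kept their calls. The amino acid list lost its call at 0.1 (camera adjusted p = 0.0682), and the identity list at 0.05 (0.125) and 0.1 (0.233). Of 17 bile acid genes 7 were lower and none higher (camera adjusted p = 0.000782, adjusted p = 0.143 with an estimated correlation), among them the bile salt export pump Abcb11 (100.1 ± 7.48 against 156 ± 10.6) and the uptake transporter Slc10a1 (237 ± 35.6 against 572 ± 112), although with equal totals 3 were lower, 1 was higher, the median was 0.17 and Abcb11 was not called (0.0984). Of 20 fatty acid oxidation genes 9 were lower (11 adjusted over the list alone; camera adjusted p = 0.000247, adjusted p = 0.554 with an estimated correlation), with Acadvl at 142 ± 10.2 against 227 ± 22.6 and Acaa2 at 424 ± 30.2 against 651 ± 48.0, and with equal totals 1 was, neither Acadvl (0.157) nor Acaa2 (0.204). Of 16 urea cycle and amino acid genes 6 were lower and 1 higher (8 and 2 adjusted over the list alone; camera adjusted p = 0.00338, adjusted p = 0.554 with an estimated correlation). With equal totals 4 were lower, 3 were higher and the median moved from -0.40 to -0.02, although camera called the list. Gls2 was 2.71-fold, Otc 1.64-fold and Arg1 2.05-fold lower. Among males alone neither the oxidation list (camera adjusted p = 0.184) nor the amino acid list (0.0687) was called. There the median of the oxidation list was -0.17, against -0.65 over all livers, and that of the amino acid list was -0.29. In WT the oxidation genes differed between the sexes by a median log2 of -0.6 (males minus females). The larger share of females in WT can therefore enter the fall of that list.

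Of 19 hepatocyte identity genes 7 were lower and 2 higher (7 and 3 adjusted over the list alone; camera adjusted p = 0.0421, adjusted p = 0.166 with an estimated correlation). Coagulation factor IX, F9, was 1.86-fold lower (85.7 ± 1.14 against 159.5 ± 10.6) and antithrombin, Serpinc1, 1.35-fold lower, a call lost among males alone (0.147) and with equal totals (0.866), where its log2 fold change was -0.03. This list lost its call without KO replicate 1 (0.0611), KO replicate 3 (0.0635), WT replicate 1 (0.0545) or WT replicate 2 (0.0568), with sex as a covariate (0.0684), among males alone (0.182), above the median abundance (0.154), on the statistics of the authors' deposited table (0.0518) and on log2 fold changes (0.19). With equal totals its counts turned to 4 higher and 1 lower and its median changed sign to 0.10.

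Lists of carbohydrate genes were not called. Of 16 glycolysis genes 5 were higher and 3 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.87), with Pkm, also a listed target, 2.28-fold higher and the liver form Pklr 2.20-fold lower, a call lost among males alone (0.145) and with equal totals (0.0759), and of 16 gluconeogenesis and glycogen genes 3 were higher and 7 lower (0.21). The brain form of glycogen phosphorylase, Pygb, was 8.47-fold higher (11.1 ± 1.42 against 1.31 ± 0.269), and the branching enzyme Gbe1 was 1.85-fold lower. The medians of both lists change sign with equal totals, where the second was called lower by camera (0.0386) although its median was 0.02, and it was also called lower with the replicate block (0.0344).

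Extracellular matrix genes and markers of several non-hepatocyte cells rose. In the matrix and fibrosis list 23 of 24 members were higher (camera adjusted p = 1.61e-13, adjusted p = 0.143 with an estimated correlation), including the fibrillar collagens Col1a1 (8.40 ± 1.04 against 1.10 ± 0.278), Col1a2 (18.6 ± 3.12 against 3.62 ± 0.643) and Col3a1 (50.6 ± 6.76 against 8.87 ± 2.05). Stellate cell markers were higher for 10 of 14 members (camera adjusted p = 0.000122, adjusted p = 0.143 with an estimated correlation), such as Cygb (4.24-fold) and Pdgfrb (2.73-fold). Macrophage and Kupffer markers were higher for 15 of 17 (camera adjusted p = 1.82e-06, adjusted p = 0.185 with an estimated correlation), with Lyz2 2.35-fold, C1qa 2.24-fold and Ccr2 4.74-fold higher. Of 6 lymphocyte markers tested, from 20 listed, 5 were higher (camera adjusted p = 0.0038, adjusted p = 0.185 with an estimated correlation). The adjusted p was 0.108 on the statistics of the authors' deposited table, whose q did not call 2 of the 5. Ltb stood at 7.09 ± 0.948 against 0.697 ± 0.387 and Cd52 at 44.8 ± 4.51 against 18.1 ± 4.38. Sinusoidal endothelial markers were not called as a list, with 2 of 13 higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.502), and their median changes sign with equal totals: Cdh5 stood at 8.20 ± 0.537 against 6.48 ± 0.467, Stab1 at 6.16 ± 1.18 against 3.69 ± 1.26 and Lyve1 at 1.15 ± 0.203 against 2.83 ± 1.04. Among males alone none of these 3 was called (0.085, 0.141 and 0.0865), and Lyve1 was not with equal totals (0.0661). The Stab1 call was also lost with sex as a covariate (0.0693) and without KO replicate 2, 3 or 4 or WT replicate 1 or 2 (0.0589 to 0.1). Of 4 neutrophil markers 3 were higher (4 adjusted over the list alone; camera adjusted p = 0.0545), and the list passed without KO replicate 1 (0.0435), KO replicate 2 (0.0493) or WT replicate 5 (0.00646), with the replicate block (0.0153), no filter (0.0229), voom (0.0396), log2 fold changes (3.54e-05) or ranks (0.0414). Of 5 erythroid markers 3 were higher (0.113), with the alpha globin Hba-a1 at 308 ± 98.9 against 143 ± 35.9 (not called among males alone, 0.0877), and the list passed without WT replicate 5 (0.042) and with the replicate block (0.0474).

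Markers of cholangiocytes and liver progenitors had the largest median change of any list, 2.38 on the log2 scale. They were higher for 8 of the 9 members tested, from 14 listed (camera adjusted p = 1.24e-05, adjusted p = 0.029 with an estimated correlation). The tight junction gene Cldn4 stood at 4.70 ± 0.305 against 0.0603 ± 0.0720, the surface antigens Cd24a at 16.6 ± 1.73 against 2.09 ± 0.299 and Epcam at 8.76 ± 1.031 against 0.885 ± 0.260. Cldn4 and Epcam, with WT means under 1, passed the filter only through their KO values. Of 10 fetal liver and oncofetal genes 5 were higher (6 adjusted over the list alone; camera adjusted p = 0.000682, adjusted p = 0.143 with an estimated correlation), led by Igf2, Meg3 and Afp, the fetal counterpart of albumin (32.2 ± 11.98 against 1.73 ± 0.184). Gpc3, a glypican, was 3.52-fold higher. H19 was not analysed here. Of 22 proliferation genes 14 were higher (18 adjusted over the list alone; camera adjusted p = 0.000429, adjusted p = 0.554 with an estimated correlation), with Cdk1 3.76-fold, Ccnb2 4.00-fold and Mcm5 2.90-fold higher. Among genes above the median abundance this list was not called (camera adjusted p = 0.229).

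Cytokine and chemokine genes were higher for 7 of 11 members (camera adjusted p = 0.00318, adjusted p = 0.143 with an estimated correlation), with Cxcl16 3.67-fold and Cxcl10 2.40-fold higher beside Ccl2, which is also a listed target. The call was lost among genes above the median abundance (0.113). Of 10 p53 and DNA damage genes 5 were higher (camera adjusted p = 0.0425, adjusted p = 0.202 with an estimated correlation), including Ccng1, also a listed target, and Gdf15 (4.89 ± 1.495 against 1.33 ± 1.06). Gdf15 was not called with a pseudocount of 0.1 (0.0563) nor in the authors' deposited table (q = 0.212). That list lost its call without KO replicate 2 (0.0616), KO replicate 4 (0.0609) or WT replicate 1 (0.0643), with sex as a covariate (0.0566), with equal totals (0.121), above the median abundance (0.0537), on the statistics of the authors' deposited table (0.0815) and on log2 fold changes (0.0566). Acute phase genes were not called (2 of 16 higher, 5 lower, camera adjusted p = 0.514), and with equal totals the balance turned to 4 higher and 1 lower (0.139): Lcn2 was 21.3-fold higher and the pentraxin Apcs 2.42-fold lower. Genes of the integrated and ER stress response (3 of 15 higher, 0.375), iron metabolism (3 of 14 higher, 1 lower, or 2 and 1 adjusted over the list alone, 0.502) and immediate early genes (3 of 9 higher, 0.137) were not called, and the last passed without WT replicate 2 (0.0189) and on log2 fold changes (0.0195). With equal totals 9 stress response genes and 9 iron genes were higher and none lower, and neither list was called. Atf3 stood at 2.84 ± 0.605 against 0.511 ± 0.494 (q = 0.0772 in the authors' deposited table), the iron regulator Hfe2, a listed target, at 78.2 ± 9.13 against 41.3 ± 6.26, Jun at 14.1 ± 3.82 against 4.11 ± 1.72 and Ier3 at 3.51 ± 0.390 against 0.610 ± 0.199. Myc (4.12 ± 3.35 against 0.712 ± 0.423) was not called without KO replicate 2, 3 or 4 or WT replicate 1, 3, 4 or 5 (0.0557 to 0.104) nor with sex as a covariate (0.0833).

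Genes of xenobiotic metabolism went both ways, with 4 of 22 higher and 4 lower (camera adjusted p = 0.87), or 8 and 2 with equal totals. The glutathione transferases Gstm3 and Gsta1, members of families with shared reads, were 9.46-fold and 14.6-fold higher. Of 12 genes of the microRNA pathway 3 were higher and none lower (camera adjusted p = 0.72), with Drosha at 3.29 ± 0.788 against 1.499 ± 0.512, Tarbp2 at 8.88 ± 0.988 against 5.86 ± 1.08 and Ago2 at 1.59 ± 0.384 against 1.72 ± 0.308 (limma adjusted p = 0.682). Neither Drosha (0.0569) nor Tarbp2 (0.0804) was called among males alone, and the median of the list changes sign with equal totals.

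Mitochondrially encoded transcripts were lower for 12 of 13 members (13 adjusted over the list alone; camera adjusted p = 2.07e-06, adjusted p = 0.24 with an estimated correlation), with mt-Co1 1.64-fold lower, whereas with equal totals 1 was and mt-Co1 was not (0.144), nor was it among males alone (0.0822) or with no filter (0.188). They made up 19.8 ± 2.42% of the listed abundance in KO and 24.0 ± 3.01% in WT libraries. Major urinary protein transcripts made up 8.22 ± 4.58% and 13.9 ± 11.3%. Cytosolic ribosomal protein genes were not called as a list (camera adjusted p = 0.411): 1 of 25 was lower and none adjusted over the list alone, but with equal totals 12 were higher and the median changed sign. The 1 called, Rpl4, was 1.21-fold lower, with near-identical pseudogene copies, and lost its call without KO replicate 2 (0.0539) or KO replicate 3 (0.0512) and among males alone (0.136), and with equal totals it was not called and lay higher in KO.

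**Figure D4:**
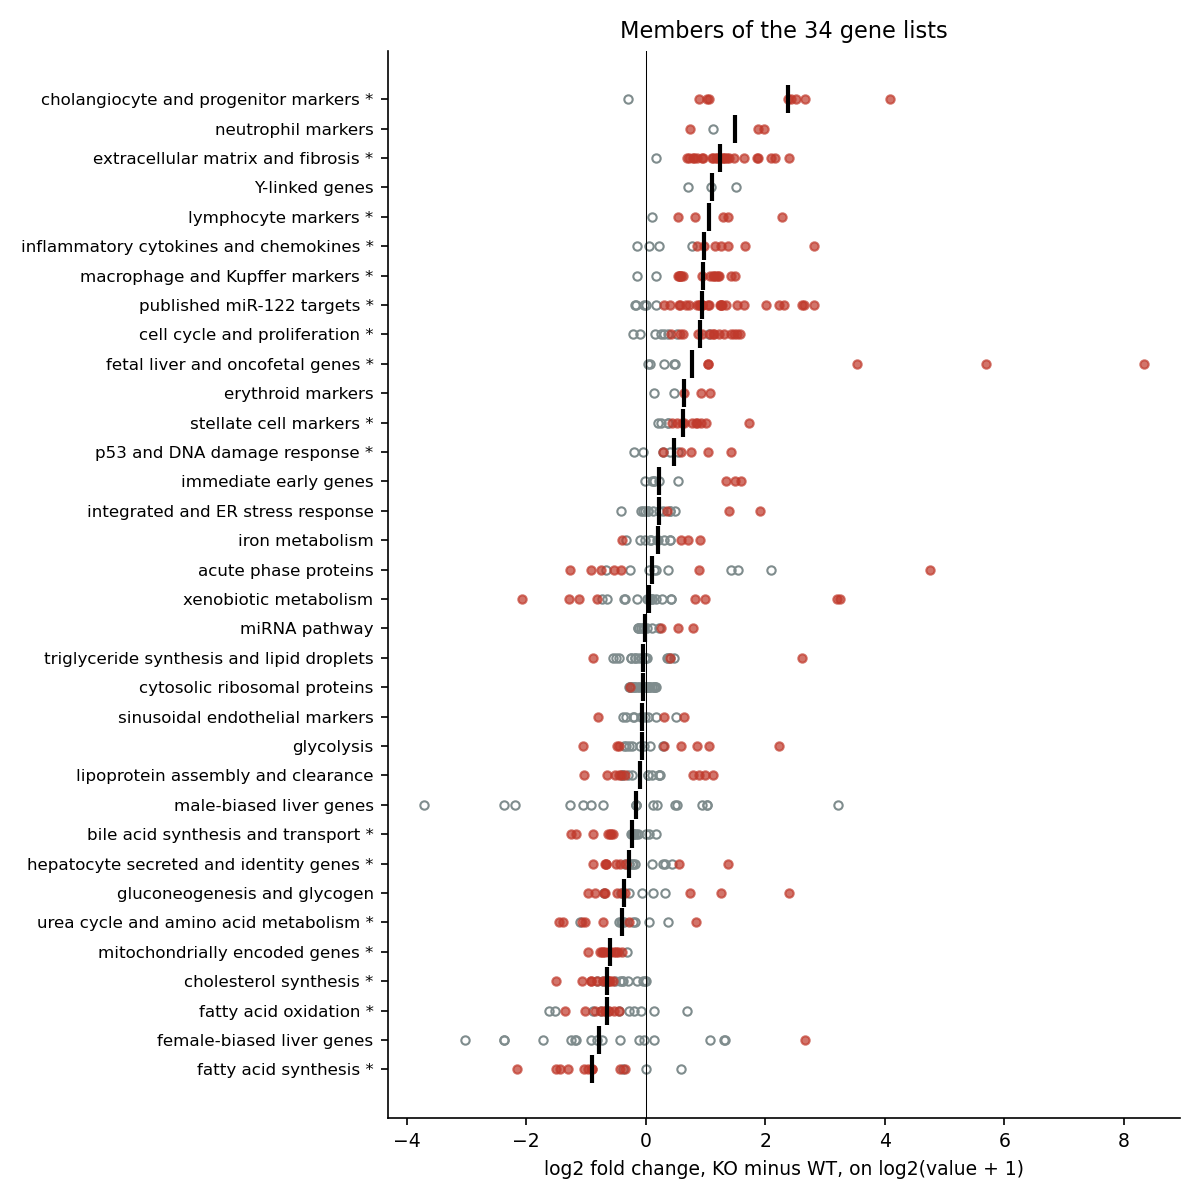
Log2 fold change, KO minus WT (x axis), of each tested member of the 34 gene lists (y axis), filled where limma called it and open where not; black bars are list medians, and an asterisk marks a list called by camera. The cholangiocyte and progenitor list has the highest median (2.38) and fatty acid synthesis the lowest (-0.90); with equal totals the median of all genes moves from 0.03 to 0.36 and the medians of several lists change sign.

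Because the genotypes differ in their share of males, genes with a known sex bias in mouse liver were examined. None of the male-biased, female-biased and Y-linked lists was called between the genotypes (camera adjusted p = 0.522, 0.485 and 0.72). The 1 member called by limma was Prom1, which is also a progenitor marker (12.6 ± 8.84 against 0.962 ± 0.509, with 25.9 in KO replicate 1). With the preset correlation, the female-biased list was called lower without WT replicate 5 (0.042) and with the replicate block (0.0106), the male-biased list was called lower with sex as a covariate (0.00316), and among males alone the female-biased list was called higher (0.00159) and the male-biased list lower (2.88e-07). With an estimated correlation neither passed among males alone (0.516 and 0.342), where none of the 34 lists did. On log2 fold changes all 3 were called (0.000161 female-biased, 0.0261 male-biased, 0.00723 Y-linked). With equal totals the female-biased and male-biased lists were called lower (0.000213 and 0.00213), although the median of the male-biased list changed sign to 0.23. A difference of the genotype effect between the sexes was tested after these results were seen. The male-biased genes differed between the sexes by a median of 3.30 on the log2 scale in WT and 1.27 in KO, and the female-biased genes by -4.67 in WT and -1.79 in KO (camera on the genotype by sex term with an estimated correlation, adjusted p = 0.57 and 0.643). The KO side of this term compares 3 males with 1 female, which has no spread of its own. Elovl3, a male-biased elongase, averaged 261 in the 2 WT males, 5.32 ± 2.92 in WT females, 1.29 ± 0.584 in KO males and 0.383 in the KO female. Cyp2b9, a female-biased P450, averaged 315 ± 90.5 in WT females, 7.68 in WT males, 138 ± 29.9 in KO males and 222 in the KO female. These 2 genes and those plotted were chosen after their values were seen.

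**Figure D5:**
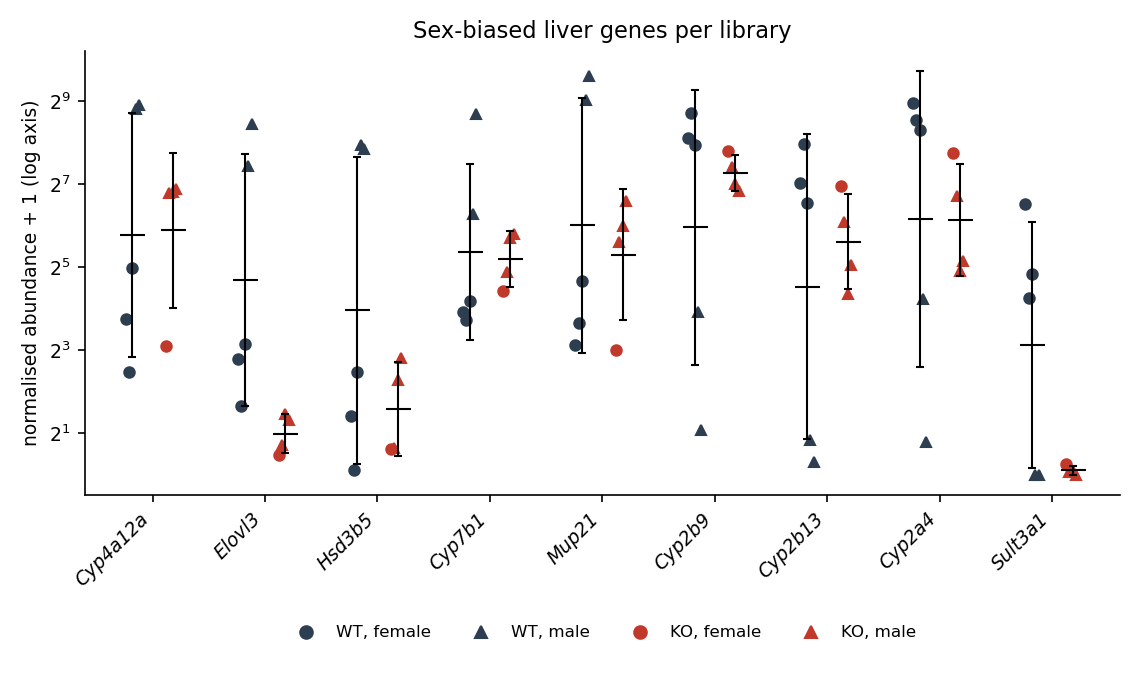
Normalised abundance plus 1 on a log axis (y) of 9 sex-biased liver genes (x) in each library; circles are females, triangles males, and black bars give the mean ± SD of log2 values over all 5 WT or 4 KO livers, both sexes together. Male-biased genes are on the left from Cyp4a12a to Mup21 and female-biased genes on the right; WT males and females lie apart, as for Cyp2a4 (9.33 in WT males, 396 in WT females), with KO livers mostly between or near the lower group.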

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

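The tests of the genotype by sex term, of the sex-biased lists among males alone and of the explanations of the sex pattern were chosen only after the result was seen; the sex-biased lists, their test between the genotypes and the splits of the libraries were planned. Of 100 splits of the 9 libraries into 4 and 5, drawn from 126, 1 called as many transcripts by limma as the genotypes, namely the genotypes themselves. They gave 3934 calls, the highest other split gave 1502 (WT replicates 1 to 4 against the rest) and the median of the others was 0. This argues against a random grouping of the libraries, which is not excluded, since the rest of the 126 splits were not run.

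Among 101 named genes and both genotypes, 19 of 202 groups held 1 library far from the others, against about 10 by chance. In WT replicate 5 this applied to Mup19 (6440, others 5.08 to 689), Eif4ebp3 (166, others up to 56.4), Lpl (32.1, others up to 21.2) and S100a9 (24.5, others up to 8.76). In the other WT livers it applied to Igf2 (2.59 in replicate 1, others up to 1.72), Acly (38.3 in replicate 1, others up to 27.1), Gls2 (77.6 in replicate 2, others up to 47.6), Agpat1 (1.99 in replicate 2, others up to 0.218), mt-Atp8 (53400 in replicate 3, others up to 47200) and Scd1 (1130 in replicate 4, others up to 695). In KO replicate 1, the only KO female, it applied to Cyp2c69 (211, others up to 12.6), Cyp2c40 (157, others up to 31.3), Prom1 (25.9, others up to 9.10), F9 (87.4, others up to 85.3) and Acaa2 (379, others at least 435.0). In the KO males it applied to Mup19 (24.6 in replicate 3, others up to 0.0335), Pkm (13.1 in replicate 3, others up to 10.2), Lyz2 (214 in replicate 4, others up to 197) and Lyve1 (0.848 in replicate 4, others at least 1.23).

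The genotype by sex term was called for 13 genes (limma, adjusted p under 0.05), and 1173 had an unadjusted p under 0.05 against 548 by chance. Each of these terms rests on the 1 KO female, which has no spread of its own, so that the spread comes from the other groups only. Named after their values were seen, Mfsd2a stood at 43.0 in WT females, 5.83 in WT males, 4.49 in the KO female and 43.5 in KO males, and Sult5a1 at 3.80, 35.1, 4.92 and 1.38. Katna1 (0.0166 in the KO female, 6.42 in KO males) and Rpl21-ps15 (13.4 in the KO female) stood out in that animal alone. The median terms, on the log2 scale with a positive sign for a higher genotype effect in males, were flagged by camera with the preset correlation at 1.06 for fatty acid oxidation, 0.52 for triglyceride and lipid droplet genes, 0.46 for urea cycle and amino acid genes, 0.36 for gluconeogenesis and glycogen, 0.20 for extracellular matrix genes, -0.38 for cholesterol synthesis, -0.70 for proliferation, -0.78 for the integrated and ER stress response and -0.56 for Y-linked genes. These tests settle no difference between the sexes, since genes that move together in 1 liver would give the same, and with an estimated correlation none of the 34 lists passed (lowest adjusted p = 0.57).

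The male-biased and female-biased lists had median genotype by sex terms of -1.61 and 2.16, and 17 of 18 and 15 of 18 members differed less in size between the sexes in KO. Low depth of both WT males is argued against by the 24 members with a mean of at least 20, whose sex difference moved against the bias of their list in KO by a median log2 of 1.94, against 1.87 over all members. A single WT male is argued against by 2.03 without WT replicate 4 and 1.39 without WT replicate 5. A male mislabelled as the KO female is argued against by Ddx3y, Uty and Eif2s3y. These 3 genes lay at 0, 0 and 0.025 in that library and at 2.36 or above in every male library. No listed Y-linked gene exceeded 0.421 in the KO female. Among males alone, which leaves out the KO female, the male-biased list was lower in KO, with a mean log2 difference of -2.09 from all other genes (camera with the preset correlation, adjusted p = 2.88e-07) and the female-biased list higher by 1.46 (0.00159). That the genotype changes sex-biased expression may explain the pattern and stays open, since the genotype by sex term rests on 1 KO female, its adjusted p with an estimated correlation were 0.57 and 0.643, and males alone leave 2 WT livers, where neither list passed with an estimated correlation (0.342 and 0.516).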

How the results depend on the processing

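Equal totals, 1 annotated transcript, the sex named by the column, the submitters' test and, for the lists, every setting that leaves out libraries or refits the model were chosen only after the result was seen. The count of 3934 called genes was 2362 (1504 higher, 858 lower) at an adjusted p of 0.01, 2551 (1196 and 1355, a balance turned to lower) above the median abundance, 1926 (1338 and 588) at 1.5-fold or more, 383 (315 and 68) by Bonferroni, 2216 (1408 and 808) among males alone and 417 (235 and 182) among 1240 genes with 1 annotated transcript; each has fewer genes, fewer samples or a stricter threshold. Equal totals gave 4926 higher and 298 lower, against 2345 and 1589. Without 1 library the calls ranged from 3170 to 3996. As reported, 17 lists were called. Above the median abundance 11 were, and the hepatocyte identity, proliferation, cytokine and p53 lists lost their calls. The other called lists missing there had under 3 tested members and so no result. The count was 2 with an estimated correlation and 0 with that among males alone. Without 1 library it was 15 to 20, including lists called only there.

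Of the 3 sex-biased lists, of which cameraPR adjusted over these 3 called none, it called 1 with sex as a covariate, 2 among males alone and 2 with equal totals. By the test over all 34 lists, log2 fold changes in place of the moderated statistic called all 3 (adjusted p = 0.0261 male-biased, 0.000161 female-biased, 0.00723 Y-linked), and the female-biased list was called lower with the replicate block (0.0106) and without WT replicate 5 (0.042). Their called members, 1 as reported, were 14 with sex as a covariate, 5 with the column's sex for WT replicate 3, 19 among males alone, 8 with the replicate block, 3 with a pseudocount of 0.1, 2 with a pseudocount of 5, 3 with no filter, 4 with equal totals, 4 by the submitters' test and 1 to 4 without 1 library. The female-biased list turned to a mean log2 of 1.46 above all other genes among males alone (adjusted p = 0.516 with an estimated correlation). With sex as a covariate it lay 0.675 above them (camera adjusted p = 0.288). Both settings take the unequal share of females into account. In WT the members of the list differed between the sexes by a median log2 of -4.67 (males minus females). The smaller share of females in KO therefore lowers the list when all livers are pooled. Explanations of the sex pattern are weighed above, and why the list lay higher in KO males stays open. Rpl4 turned from -0.27 to 0.13 with equal totals, a scaling that raises KO against WT values.

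With the replicate block the calls were 3552 (2142 higher, 1410 lower). Deviations of libraries with the same number correlated at 0.23, 0.08, -0.18 and 0.11. Sex enters these values: KO replicate 1, a female, correlated at 0.23, 0.19 and 0.18 with WT females and at -0.19 and -0.27 with WT males. The male KO replicates 3 and 4 went with the WT males (0.11 to 0.23), but the male KO replicate 2 did not (-0.04 and -0.12). Whether the numbers pair the animals is therefore not settled. Over all alternatives, the 101 named genes kept their direction and side of the threshold in 2231 comparisons, lost the call in 151, moved in 3 and reversed in 1, and the 34 lists did so in 755, 61, 40 and 1, with a call gained in 23. The shift of genes with a seed site had a permutation p of 0.0001, the smallest possible, in every setting run. The alternatives that choose among several transcripts of a gene were not run, since each gene has 1. Depth of 12.2 to 22.0 M reads limits genes near the filter.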

Other observations

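The tests of the cell type markers were chosen only after the result was seen, as was the list of imprinted genes, assembled once Igf2, Meg3 and Peg3 had been seen. Of 26 imprinted genes outside the fixed lists, 11 were tested. Of these, 8 were higher in KO and 1 was lower (the same counts adjusted over the list alone). Their median log2 fold change was 0.50 (camera p = 0.00488, p = 0.0337 with an estimated correlation). Grb10 and Ppp1r9a, with WT means under 1, passed the filter only through their KO values, which favours increases. The epsilon-sarcoglycan gene Sgce stood at 14.1 ± 1.90 against 3.45 ± 0.548, the adaptor gene Grb10 at 4.39 ± 2.496 against 0.635 ± 0.644 and the Igf2 receptor gene Igf2r at 8.31 ± 1.12 against 4.28 ± 0.456. Tssc4 was lower (2.71 ± 1.54 against 5.29 ± 0.9705), and Slc38a4 stood at 275.1 ± 61.2 against 282.9 ± 25.3. The fixed fetal list holds further imprinted genes, Dlk1, Mest, Plagl1 and Cdkn1c. None of them was among its 5 called members, and the test of imprinted genes leaves them out. A hypothesis is that imprinted genes may rise together with Igf2 and Meg3, and the median of 0.50 lay above the 0.2 set as its lower limit.

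Stellate, macrophage, lymphocyte and cholangiocyte markers had higher list means in KO, by log2 of 0.68, 0.84, 1.07 and 1.86 (two-sided exact permutation p = 0.00794, the smallest possible), whereas endothelial markers differed by -0.03 (exact permutation p = 0.722). A lower share of hepatocyte RNA by itself would raise all of them alike. As the only cause it is argued against by gaps to the endothelial markers of 0.72 for stellate and 0.87 for macrophage markers (exact permutation p = 0.00794 each). The endothelial list was taken as the reference after its result was seen. The gaps therefore cannot exclude a lower share of hepatocyte RNA beside a change of the endothelial markers. Scaling is argued against by the marker median, 0.85 above that of all genes. A factor per library moves all its genes nearly alike, so the 0.80 found with equal totals is not separate evidence. More reads in KO are argued against by a median of 0.61 over the 16 markers with a mean of at least 10. More cells of the types that rose, or more of these transcripts per cell, were not separated, and either may account for the pattern.

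The table holds 93.0% of the 100 transcripts with the smallest p and 32.2% of those ranked past 20000. If the transcript with the smallest p had been kept for each gene, genes with 5 or more annotated transcripts would need at least 1.5 times as many p from 0.5 to 0.75 as above 0.75. The ratio was 1.14 (95% interval from 1.04 to a value below 1.5), against 1 (0.83 to 1.21) for genes with 1 transcript, which argues against that choice. This reading was settled after the ratio was seen, and the upper end of the interval just passes the limit that had been set in advance for excluding it. That the most abundant transcript was kept may hold, and at 1.14 it cannot be told apart from other choices that do not look at p.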
